A study of Glycine max with 8 samples.

How the data were processed

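RNA-seq libraries from soybean seedlings were analysed, 8 in total, covering 2 genotypes, 2 treatments and 2 libraries per group. Per the labels' protocols, seeds germinated on moist paper, and seedlings grew hydroponically in dilute Hoagland solution under a 16 h photoperiod at 28 °C in light and 20 °C in darkness for 2 weeks. NaCl was added to 150 mM for 6 h. Root and leaf RNA was extracted with a column kit and pooled in equal parts, and barcoded Illumina mRNA libraries were made. A value is therefore an average over both organs, and a change in one organ is diluted by the other.

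The deposited files give an expected count for each gene model, an estimate that need not be whole because reads that fit several models are divided among them. RSEM made these values, per the submitters' processing notes; its version, the aligner, the read length, strandedness, the genome build and the annotation release are not given in the sources used here. Per the file headers, each file also holds an FPKM value and a length for every model, and the FPKM values were not used for any test. All lengths were multiples of 3, so they are coding lengths without untranslated regions, and reads from those regions may not have been counted. Only models with an expected count of at least 0.01 are listed in the deposited files, so a model absent from a file was set to 0. Together the files list 74813 models at 47268 loci. The column for length was used only to describe loci.

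Expected counts were summed over the models of a locus, whose IDs differ only in their final number, and rounded to whole numbers. This sum was chosen after the files were seen, because the planned design spoke of genes, and models as units were run as an alternative. Chromosomes and neighbouring loci were read from the locus IDs. Total expected counts were 5980170 to 7199780 per library, at which a locus with 3 counts lies below 1 CPM. At this depth rare transcripts are measured with large counting error, and a count of 0 allows up to 3 counts. Intervals and floors cover counting error only. Only 12.9% of tested loci had whole counts in all 8 libraries within a tolerance of 0.01; the others share reads with further models, so levels of near-identical copies are uncertain.

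Groups and replicate numbers were taken from the labels. Nothing in the labels says whether libraries of one group came from separate plants or pools of plants beyond calling them biological replicates, so p-values measure only the spread between these libraries. With groups of 2, the pooled fit has 4 residual degrees of freedom.

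Loci were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, 1 coefficient per group, all 8 libraries), which left 34023 loci. Benjamini-Hochberg adjustment was applied per comparison with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. The comparisons were NaCl against mock in each genotype, OE against WT in each treatment, the interaction, and the overlap of calls. Floors for a group with 0 counts were set at 3 counts over the group's libraries. Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 2 libraries and a total of 40), DESeq2 1.42.0, limma-voom (limma 3.58.1), a 2-fold minimum, a replicate block, fits of only the 4 libraries compared, and each library left out in turn. Added after the data were seen were models as units, fits without the OE libraries numbered 1 or 2, voom with a weight per genotype, the replicate block within OE libraries, and variants of the counts for WT libraries alone and for loci seen in 1 genotype.

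The BCV of a pair of libraries was edgeR's common dispersion (its square root) over loci with at least 50 counts in the pair. Groupings of 2 against 2 libraries by replicate number, and crossed, were fitted like the treatment grouping and were chosen after the data were seen. So were the tests of chromosomes and neighbours and the summaries of abundance and coding length, which were not tested. The scripts were tested on simulated counts with the real libraries' sizes, in which 70 loci each were changed by 2-fold, 4-fold and 16-fold. The changed loci were drawn from those with a mean of at least 4 CPM. For salt, unchanged means were shared within a genotype, and for genotype over all groups. Spread followed each genotype's trend with abundance. Libraries were drawn independently, so the joint deviations of OE libraries of equal number were not simulated. For genotype in mock, the fit of all libraries recovered 0, 9 and 51 of the changed loci with 1 false call. The fit of only the 4 mock libraries recovered 0 at each size. On the real counts it called 3317 loci, so its simulated recovery does not carry over. For salt in OE, the fit of all libraries recovered 2, 27 and 61 and made 51 false calls.

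The reference gene table (Glycine_max_v4.0 assembly) was used for names only, and 0 of the locus IDs matched it. For that reason none of the 35 gene lists fixed beforehand (salt, abscisic acid, reactive oxygen, growth, and leaf, root and nodule markers) could be formed, and list tests, the leaf-minus-root covariate and scaling without leaf markers were not run. Root and leaf shares of the mixtures were therefore not checked. The rule for named loci kept those past the threshold with a change of 2-fold or more, a mean of at least 4 CPM over all libraries and no overlap between the groups' libraries, ranked by log2 fold change. Its further condition, a known description, could not be applied. Of each ranking in mock seedlings the first 2 loci are named, and the same 4 were followed in NaCl.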

Results

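The series measured polyadenylated transcripts by RNA-seq in seedlings of soybean (Glycine max) of 2 genotypes. One was the conventional line WEI6823, wild type for GmSIN1 (WT). The other over-expressed GmSIN1 (OE), a NAC transcription factor gene. Seedlings grown in hydroponic solution for 2 weeks received 150 mM NaCl or a mock treatment for 6 h, and RNA from roots and from leaves was mixed in equal amounts before library preparation. Each of the 4 groups held 2 libraries, numbered 1 and 2. Total expected counts lay between 5980170 and 7199780 per library, and 34023 loci passed the abundance filter. The files do not pair their locus IDs with gene names, so loci are described by ID, chromosome and group, and only 4 IDs are printed.

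The 4 WT libraries resembled each other closely whether or not the seedlings had received NaCl. The biological coefficient of variation (BCV), the spread between libraries beyond counting noise, was 3.84% between the WT mock libraries and 3.18% between the WT NaCl libraries. The 4 pairs of a WT mock with a WT NaCl library had values of 3.33% to 5.10%. Loci in OE seedlings varied far more between libraries of one group, with a BCV of 40.1% between the OE mock libraries and 48.4% between the OE NaCl libraries. OE libraries of equal number were closer across treatments, at 27.5% for the pair numbered 1 and 8.13% for the pair numbered 2. Pairs of a WT with an OE library had values of 41.8% to 60.3%. OE NaCl library 1 lay nearer to the WT libraries (44.7% to 45.1%) than to OE NaCl library 2 (48.4%). OE mock library 1 lay about as far from the WT libraries (41.8% to 42.3%) as from OE mock library 2 (40.1%). In every pair the counts differed by more than sampling noise, with a chi-square per degree of freedom of 1.36 in the closest pair, so no pair was merged as a library deposited again. This does not show that the libraries came from separate RNA samples. The first principal component of log2 CPM (counts scaled to the library total) held 72.1% of the variance and placed the WT libraries between -75.9 and -74.7. It placed OE mock libraries 1 and 2 at 41.3 and 119, and OE NaCl libraries 1 and 2 at 24.5 and 116.

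**Figure D1:**
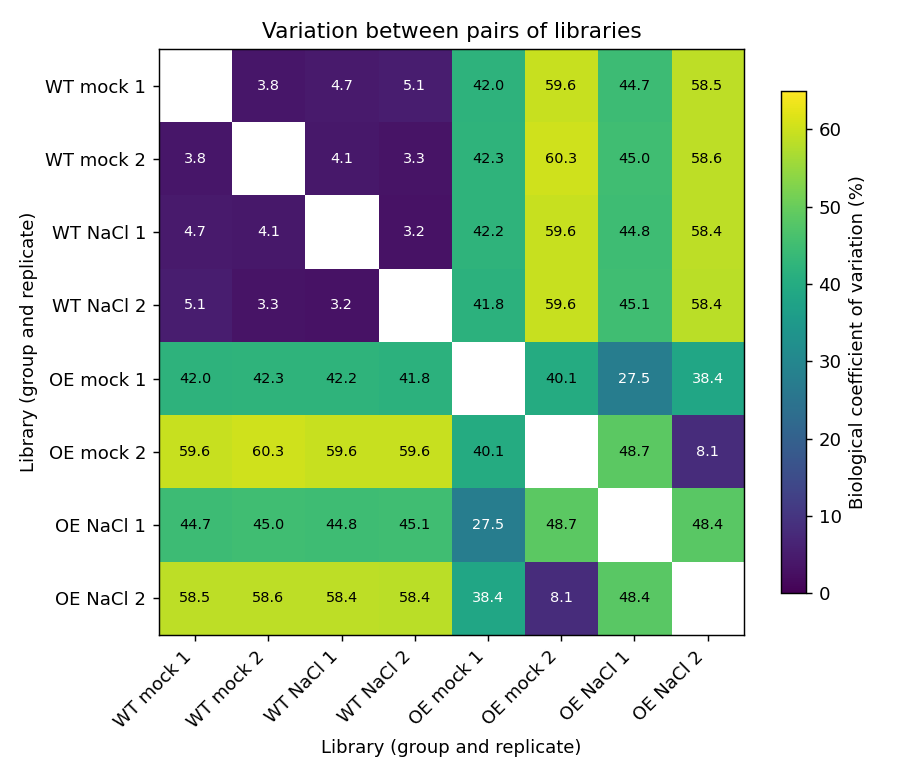
Biological coefficient of variation (%) for each pair of the 8 libraries, named by group and replicate on both axes, over loci with at least 50 counts in the pair. The 6 WT pairs lie between 3.18% and 5.10%, and the OE libraries numbered 2 differ from each other by 8.13% but from the OE libraries numbered 1 by 38.4% or more.

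The first comparison asked which transcripts responded to 150 mM NaCl in WT seedlings. Among the 18160 loci at 10 CPM or more, 0 changed by 2-fold between WT mock and WT NaCl. The log2 fold changes of these loci had an SD of 0.138, against 0.133 when the same libraries were grouped by replicate number. When the 4 WT libraries were fitted alone with edgeR's quasi-likelihood test, 15 of 30986 loci passed an adjusted p of 0.05, of which 12 were higher and 3 lower in NaCl. In this fit 2036 loci had an unadjusted p under 0.05 against 1549 expected by chance, and the same libraries grouped by replicate number or crossed gave 1351 and 1215. Only 3 of the 15 called loci changed by 2-fold or more, and 8 changed by less than 1.5-fold. One of them, on chromosome 13 and picked out after its values were seen, had 0 counts in both WT mock libraries and 71.9 and 43.3 expected counts in WT NaCl libraries 1 and 2. It also had 0 counts in all 4 OE libraries, and its fractional counts mean that its reads were shared with other gene models. With 1 spread estimated over all 8 libraries, the design fixed before the data were examined, edgeR called 0 of 34023 loci. In that fit 111 loci had an unadjusted p under 0.05, where 1701 would be expected by chance if all groups varied equally. They did not: its common BCV, 0.329 as a fraction, lay far above that within WT groups and below that within OE groups. The number expected by chance is therefore no null for this fit. DESeq2 and limma-voom also called 0. On simulated counts the fit over all libraries recovered 0 of 70 loci changed 2-fold and 10 of 70 changed 4-fold. The fit of the WT libraries alone recovered 60 and 69 of these and made 10 false calls. Its count of 15 became 1 with DESeq2, 5 with upper-quartile scaling and 73 without a filter, and 106, 60 and 54 without WT mock library 2, WT NaCl library 1 and WT NaCl library 2. Grouping the WT libraries by replicate number called 45 loci.

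The same question in OE seedlings gave no locus that passed the test. Among 18576 loci at 10 CPM or more, 131 (0.705%) differed by 2-fold between the OE mock and OE NaCl means, and the log2 fold changes had an SD of 0.302. Pairs of equal number have 1 library per treatment, so a salt change within a pair cannot be parted from variation between libraries. Between the OE libraries numbered 1, 1078 of 18521 loci changed by 2-fold or more on the log2(CPM + 1) scale, 227 being higher and 851 lower in NaCl. Between those numbered 2, 20 loci did, 14 higher and 6 lower. Only 1 locus changed by 2-fold in the same direction in both pairs, and across loci, which are not independent replicates, the changes had a Pearson r of -0.00789. With all 8 libraries edgeR called 0 loci, and DESeq2 and limma-voom called 0. In the edgeR fit 507 loci had an unadjusted p under 0.05, against 1701 by chance if all groups varied equally, which they did not. Fitting the 4 OE libraries alone also called 0, with 27 of 32629 loci under an unadjusted p of 0.05. This fit recovered 1, 11 and 62 of 70 simulated loci changed by 2-fold, 4-fold and 16-fold, so simulated changes of 4-fold or less were mostly missed. Without OE NaCl library 2 the fit of the other 7 libraries called 218 loci, with the lone OE NaCl library assumed to vary like the other groups.

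**Figure D2:**
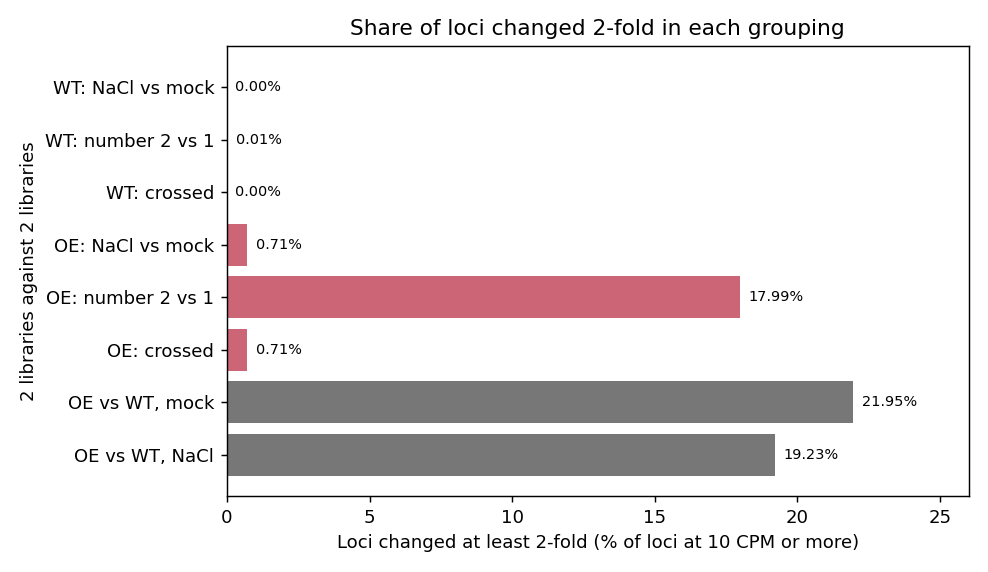
Percentage of loci at 10 CPM or more (horizontal axis) whose means differ by at least 2-fold when 2 libraries are set against 2 others; WT groupings come first, then OE, then the genotype comparisons, and "crossed" sets mock 1 and NaCl 2 against mock 2 and NaCl 1. Grouping the OE libraries by replicate number gives 18.0%, by treatment 0.705%, and the genotype comparisons give 22.0% and 19.2%.

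Whether GmSIN1 over-expression altered the salt response was tested as the interaction of genotype and treatment. No locus passed it: edgeR called 0 of 34023 loci, and DESeq2 and limma-voom called 0. In the edgeR fit 232 loci had an unadjusted p under 0.05, against 1701 by chance if all groups varied equally, which they did not. The interaction was not simulated. For salt, the same edgeR fit recovered 0 of 70 simulated 2-fold changes in WT and 2 of 70 in OE. An altered salt response is therefore not excluded. Since neither genotype had a called locus in the fit of all libraries, 0 salt calls were shared. Without OE NaCl library 2 the interaction called 57 loci.

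Genotype divided the transcriptome more than treatment did. In mock-treated seedlings 1430 loci were higher and 1608 lower in OE than in WT at an adjusted p of 0.05 in edgeR's quasi-likelihood test, together 8.93% of the loci tested. Of these, 2693 differed by 2-fold or more. Genotype tests in both treatments used the 1 spread over all 8 libraries, although WT and OE groups varied unequally. Which direction held more loci turned with the setting, DESeq2 giving 3102 higher and 2044 lower loci and RLE scaling 1509 and 1478. In OE mock library 1 the higher loci had a median change from the WT mean of 1.58 and the lower loci of -1.34 on the log2(CPM + 1) scale. In OE mock library 2 these medians were 1.91 and -1.43. Loci were ranked by fitted log2 fold change, which is no bound where a group has 0 counts. A locus with 5771 counts in OE mock and 6 in WT mock ranked 11 among the higher loci, behind loci with 0 counts in WT mock. The highest-ranked locus, Glyma.10G060800 on chromosome 10 (longest coding length 792 bases), reached 92.9 ± 71.4 CPM (SD, n = 2) in OE and had 0 counts in WT mock. This is at least 403-fold higher when WT is set at 3 counts over the group (adjusted p = 0.0194). Its level in OE mock library 1 was 42.4 CPM, or at least 184-fold higher, and in library 2 143 CPM, or at least 623-fold.

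Glyma.03G143700 on chromosome 3 (coding length 1530 bases) was next among the higher loci, with 65.9 ± 73.5 CPM (SD, n = 2) in OE mock and 0 counts in WT mock, at least 286-fold higher (edgeR adjusted p = 0.0388). The bound differed between the OE libraries, at 60.7-fold from library 1 and 512-fold from library 2. Among the lower loci, Glyma.U002100, which its ID places on a scaffold outside the chromosomes (coding length 2799 bases), ranked first by fitted log2 fold change. It had 9.45 ± 3.36 CPM (SD, n = 2) in WT mock and 0 counts in OE mock, at least 40.8-fold lower (edgeR adjusted p = 0.0169). Its rank rests on the fit at 0 counts. The locus ranked next had a ratio per effective library size of 345, with an exact 95% counting interval of 134 to 1266. Glyma.13G095000 on chromosome 13 (coding length 864 bases) fell from 106 ± 3.28 CPM in WT mock to 0.315 ± 0.235 CPM in OE mock (SD, n = 2 each), a log2 fold change of -8.34 with a standard error of 0.40 (edgeR adjusted p = 0.0028). It was -7.74 without OE mock library 1 and -9.31 without library 2. All 4 of these loci carry fractional counts, so their reads were partly shared with other gene models and their levels are uncertain to that extent. The number of called loci moved with the libraries in the fit: it was 1 when either WT mock library was left out, 428 and 409 without WT NaCl library 1 or 2, 739 without OE mock library 2, and 7964 and 8129 without OE NaCl library 1 or 2. All 4 named loci lost their call when either WT mock library was left out. Glyma.10G060800 also lost it with limma-voom, and Glyma.U002100 with a weight per genotype and without OE mock library 2 or either WT NaCl library. Glyma.03G143700 lost it in 7 of 19 refits (adjusted p up to 0.292 with limma-voom; log2 fold changes of 9.03 to 12.62), among them those without OE mock library 2, without either WT NaCl library and with only the 4 mock libraries.

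**Figure D3:**
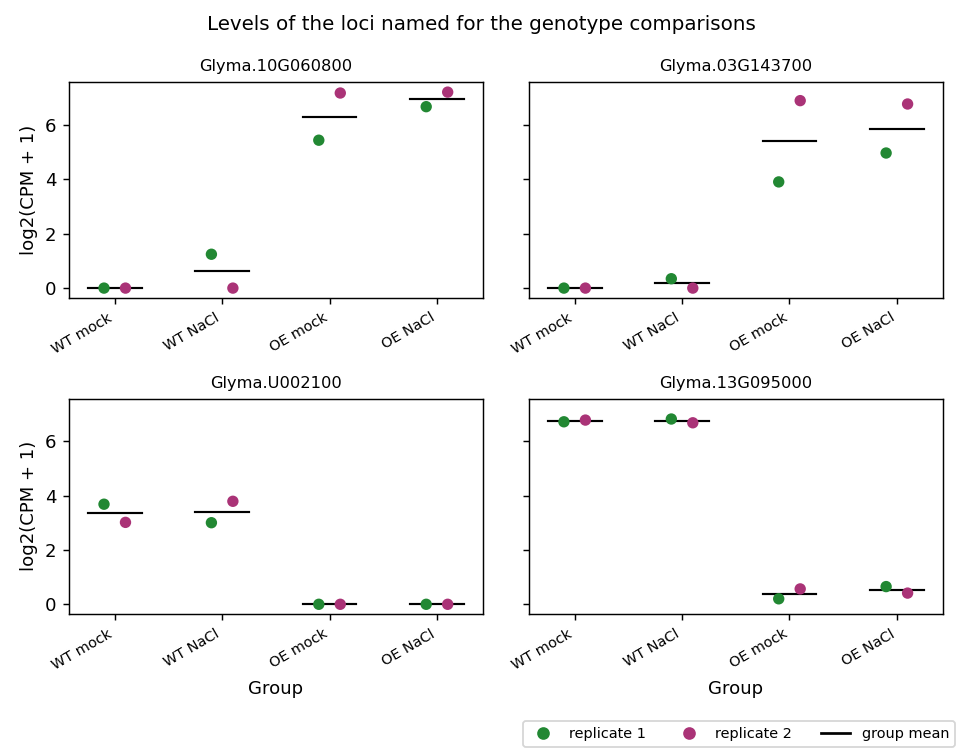
Levels of the 4 named loci as log2(CPM + 1) on the vertical axis in each group, with a point per library (green, replicate 1; purple, replicate 2) and a line at the group mean of these values. Glyma.13G095000 lies near 106 CPM in WT groups and below 1 CPM in OE groups, while Glyma.03G143700 differs between OE mock libraries 1 and 2 (14.0 and 118 CPM).

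In NaCl-treated seedlings the genotypes again differed at many loci, 1233 higher and 1452 lower in OE (edgeR adjusted p of 0.05), or 7.89% of those tested. A change of 2-fold or more was found at 2417 of these 2685 loci. DESeq2 gave 2819 higher and 1801 lower loci and RLE scaling 1312 and 1277. In OE NaCl library 1 the higher loci had a median change from the WT NaCl mean of 1.78 and the lower loci of -1.39 on the log2(CPM + 1) scale, and in library 2 of 1.92 and -1.43. Glyma.10G060800 was at 124 ± 32.4 CPM in OE NaCl and 0.686 ± 0.971 CPM in WT NaCl (SD, n = 2 each), a log2 fold change of 7.43 with a standard error of 1.15 (edgeR adjusted p = 0.0231). All 10 of its WT NaCl counts lay in library 1. The log2 fold change was 6.48 without WT NaCl library 2, and without library 1, where WT NaCl is at 0 counts, the fitted value of 12.67 is no bound. Glyma.03G143700 had 876 counts in OE NaCl and 2 in WT NaCl, a ratio per effective library size of 470 with an exact 95% counting interval of 130 to 3889 (edgeR adjusted p = 0.0429). Both WT counts lay in library 1, and the OE libraries were at 30.3 and 108 CPM. Its fitted log2 fold change, 8.76 with a standard error of 1.77, was 7.87 without WT NaCl library 2, 7.56 without OE NaCl library 2 and 9.40 without OE NaCl library 1, and the 11.83 without WT NaCl library 1 is again no bound. Glyma.U002100 again had 0 counts in OE and 9.90 ± 4.11 CPM (SD, n = 2) in WT, at least 43.5-fold lower (edgeR adjusted p = 0.0164). Glyma.13G095000 was at 106 ± 7.29 CPM in WT NaCl and 0.446 ± 0.169 CPM in OE NaCl (SD, n = 2 each), a log2 fold change of -7.82 with a standard error of 0.38 (edgeR adjusted p = 0.00267). All 4 loci lost their call when either WT NaCl library was left out, and all but Glyma.13G095000 when either WT mock library was or with only the 4 NaCl libraries. Limma-voom ended it for Glyma.10G060800 and Glyma.03G143700, a weight per genotype for Glyma.U002100, and leaving out OE NaCl library 2 for Glyma.03G143700. Fitting only the 4 NaCl libraries called 173 loci in all. The count was 0 when either WT NaCl library was left out, 520 and 516 without WT mock library 1 or 2, and 7204 without OE NaCl library 1.

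Loci that separated the genotypes were largely shared between treatments. Of the higher loci 935 were called in both mock and NaCl, where 51.8 would overlap if the lists were independent, and of the lower loci 1139, against 68.6. Not a single locus was called in opposite directions (0 against 61.0). These values for independent lists are no null for the overlap. The comparisons share no library, but they share 1 spread estimate per locus, and OE libraries of equal number deviated together across treatments (r = 0.761 across loci). Across all 34023 loci their log2 fold changes had a Pearson r of 0.921 and a Spearman rho of 0.867. The count of 2074 shared calls became 0 when either WT NaCl library was left out, 1 when either WT mock library was, 688 without OE mock library 2 and 5557 without OE NaCl library 1.

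Shared loci were spread over the 20 chromosomes. The share of tested loci that was higher in OE in both treatments lay between 1.71% and 3.41% per chromosome, and the share that was lower between 2.13% and 4.09%. None of the 40 two-sided Fisher's exact tests of a chromosome against the rest passed adjustment, the lowest adjusted p being 0.171 for fewer lower loci on chromosome 5 (34 loci, 2.13% against 3.41% elsewhere). Neighbouring loci were nevertheless called together more often than in shuffled orders within chromosomes. Higher loci formed 57 neighbouring pairs against a mean of 25.6 and a maximum of 46 in 1000 permutations, and lower loci 69 against 37.6 and 59. Both permutation p-values were 0.000999, the smallest that 1000 permutations can give. Neighbouring copies that divide the same reads would be called together, and such copies were counted as separate loci. The pairs therefore need not be separate transcripts that changed together. The longest run of higher loci held 4 on chromosome 8, and that of lower loci 5 on chromosome 17.

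Abundance differed between the directions in the main edgeR fit, though no test was made of this. The balance of directions turned with the tool, and the quartiles were not repeated with other tools. In the lowest abundance quartile of the tested loci, 0.482 to 4.29 CPM, 157 shared loci were higher and 52 lower in OE. The next quartiles held 256 higher and 162 lower loci, then 246 and 392. In the highest quartile, from 28.2 CPM upward, 276 were higher and 533 lower. Median coding length was 1167 bases for the higher loci, 1305 for the lower loci and 1179 for all others.

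The over-expressed gene itself could not be followed. The reference gene table lists a gene with the synonym SIN1, under the symbol NAC27, on chromosome 13 without a locus ID of the kind used in the files, so GmSIN1 was not assigned to a locus and its level was not analysed here. Of the 2432 loci tested on chromosome 13, 62 were higher and 87 lower in OE in both treatments.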

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

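The fits without several libraries, with models as units, with a weight per genotype and with a block within OE libraries, the variants of the count in WT libraries alone, and all counts of loci by number or seen in 1 genotype were chosen after the data were seen. The others were planned. RLE and upper-quartile scaling, both filters, limma-voom, a 2-fold minimum and the weight per genotype kept all 7 counts of calls within 1.5 times, from 2271 to 4224 for genotype in mock and from 2093 to 3580 in NaCl. The share of genotype calls that were higher in OE, 47.1% in mock and 45.9% in NaCl, was 60.3% and 61.0% with DESeq2, 36.3% and 33.9% with limma-voom, and 62.6% and 59.1% with the weight per genotype, so neither direction prevailed under all tools. With RLE scaling it was 50.5% and 50.7%. DESeq2 called 5146 loci for genotype in mock, 4620 in NaCl and 3620 in both. Models as units gave 1193, 1076 and 798. Only the 4 libraries compared gave 15 loci for salt in WT and 173 for genotype in NaCl. A replicate block gave 4670, 4116 and 3217 for genotype and 44 for WT libraries alone (15 without it), and 0 for salt in OE, also within OE libraries alone. Replicate numbers deviated together between OE mock and OE NaCl (r = 0.761 across loci) but not in the other 5 pairs of groups (-0.0151 to 0.00789). Only the OE libraries thus went together by number, which a pairing or exchanged treatment labels would both give. Without the OE libraries numbered 1, calls were 18 for salt in WT, 509 for salt in OE, 198 for the interaction, 19590 and 19354 for genotype in mock and NaCl, 2 shared for salt and 16049 shared for genotype. Without those numbered 2 they were 19, 7802, 5468, 16306, 16171, 2 and 10307. Both of these fits leave 1 library in each OE group, which is then assumed to vary like the WT libraries, so their counts have no check within OE. Leaving out 1 library at a time gave 0 to 0 for salt in WT, 0 to 218 for salt in OE, 0 to 57 for the interaction, 1 to 8129 for genotype in mock, 0 to 7204 in NaCl, 0 to 0 shared for salt and 0 to 5557 shared for genotype. In WT libraries alone salt gave 5 loci with upper-quartile scaling, 73 without a filter, 1 with DESeq2 and 21 to 106 with 1 library left out. The cause of these shifts was not tested. For the 4 named loci in both treatments, refits gave 152 tests with 0 reversed directions, of which 113 kept the call and 39 lost it (adjusted p up to 0.343). These loci were picked for extreme changes in the same libraries, so the lack of reversals is no sign of stability. Loci that differed by number in OE fell from 6992 to 2941 without a filter. Loci seen in OE alone numbered 208, and 89 at exactly 0 counts, 103 at 10 CPM, 436 at 2 CPM and 319 as models, against 1 seen in WT alone and 0 to 76 under the same variants. The leaf-minus-root covariate, scaling without leaf markers and all list tests were not run because no list could be formed. At this depth and spread, the fit of all libraries recovered simulated salt changes in OE at 61 of 70 loci for 16-fold and at 2 of 70 for 2-fold.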

Other observations

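The fit of the 4 WT libraries alone by treatment and the genotype fit were planned. The other tests below were chosen after the patterns were seen, and among them the results of the tests of a mixture and of neighbouring pairs were not known when their outcomes were laid out.

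A set of 208 loci had at most 3 counts summed over the 4 WT libraries and a mean of at least 5 CPM over the 4 OE libraries, while 1 locus showed the opposite. The 208 loci lay on all 20 chromosomes, with at most 17 on any one, and 1 lay on a scaffold. Their median level was 2.38 CPM in OE mock library 1, 17.1 in OE mock library 2, 4.67 in OE NaCl library 1 and 14.8 in OE NaCl library 2. Of these loci 193 were higher in number 2 than in number 1 among the mock libraries and 178 among the NaCl libraries. In edgeR's fit 69 passed the genotype test in mock, 74 in NaCl and 66 in both. Only 53 had whole counts in all libraries, so the others shared reads with further models. Some loci on chromosome 13 had equal rounded levels in every library, for example 2.97 and 17.3 CPM in OE mock libraries 1 and 2. Copies that divide the same reads would give this, and such loci are counted separately here and below.

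These 208 loci were weighed against technical causes. Depth is argued against, since the WT libraries held 100.2% of the counts of the OE libraries, and only 1 of the 35 splits of the 8 libraries into 4 and 4, the genotype split, gave as many loci on one side (highest other split 22). Libraries of equal number in OE deviated together, and all those of WT were much alike. Independence of the libraries is not shown, so the count of splits does not exclude chance differences between a few RNA sources. A tissue absent from the WT samples and present at differing shares in OE samples would keep these loci in one ratio, but across loci the levels of OE mock libraries 1 and 2 had r = 0.163 (95% bootstrap interval 0.0123 to 0.310), while equal numbers had 0.932 and 0.971. The loci were chosen by their mean over the OE libraries, which may itself have lowered r between numbers. The loci formed 14 neighbouring pairs against a mean of 0.919 when shuffled among all 47268 listed loci. These include loci below 5 CPM in OE, so 0.919 may be too low. Tandem copies or genome segments may underlie part of the 208 loci. When only loci at 5 CPM or more in OE counted as neighbours, 171 of 207 on chromosomes stood alone, which argues against segments as the whole cause. A difference in genetic background between the lines, beyond the transgene, stays open and was not tested.

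The WT mock and WT NaCl libraries were nearly as alike as replicates, which is surprising for 6 h in 150 mM NaCl. Too little power is argued against only for loci at 4 CPM or more and at the spread between these 4 libraries. Their fit called 15 loci while recovering 85.7% of simulated 2-fold changes. The simulated spread was taken from the same 4 libraries, so power between separate RNA samples is not shown. The highest BCV of a mock and NaCl pair was 5.10%, against 3.84% within WT mock. No libraries known to share an RNA source were at hand for comparison, so 1 RNA source behind the 4 libraries stays open. The labelled grouping of the WT libraries nevertheless had 2036 loci at an unadjusted p under 0.05 (1549 by chance). In it 1 locus had 0 counts in both mock libraries and 71.9 and 43.3 in NaCl. Labels exchanged among these libraries are argued against only as hiding a strong response. No grouping of the 4 had more than 2 loci changed by 2-fold at 10 CPM or more. Smaller differences do not decide it, since the measures go opposite ways. The other groupings had 1351 and 1215 loci at an unadjusted p under 0.05, but grouping by number called 45 loci against 15. A true lack of a strong response in WT seedlings would give a like SD of log2 fold changes, 0.138, so it and 1 RNA source cannot be told apart here, no salt-responsive genes being matched to IDs.

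Libraries of OE seedlings parted by replicate number rather than by treatment. Depth is argued against, since library 2 held 106.8% of the counts of library 1 in OE mock and 96.5% in OE NaCl. A mixture of WT RNA with that of the libraries numbered 2 is argued against as the source of those numbered 1, because 27.2% of the loci that differed by number (1900 loci) lay more than 1.5-fold outside the range between them, 1324 above and 576 below. Grouping by number called 6992 loci and the other 2 groupings of the 4 libraries 0, as exchanged treatment labels of 2 OE libraries would give, although the 3 possible groupings are too few for a share under 0.05. An exchange would make libraries of equal number replicates of the same group. Those numbered 2 had a BCV of 8.13%. Those numbered 1 had 27.5%, with 227 loci at least 2-fold higher and 851 lower in the library labelled NaCl, which a plain exchange leaves unexplained. Separate transgenic lines, plant pools or harvests behind the numbers may also be the source and were not tested, and no label was changed.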
